A study of Homo sapiens with 8 samples.

How the data were processed

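RNA was measured in 8 libraries of human prostate cancer cells: LNCaP and PC3, each as control and with miR-375 overexpressed, 2 libraries per group. Groups and replicate numbers were taken from the sample titles. How miR-375 was raised, for how long, and what the controls received is not given in the sources used here. Per the labels' protocols, cells grew in RPMI-1640 with 10% (LNCaP) or 20% (PC3) serum, so line and serum share cannot be separated in any comparison of lines. Poly(A) RNA was selected with oligo(dT) beads, fragmented, and made into dUTP-marked stranded libraries that were read as 150-base pairs on an Illumina sequencer, per the labels' protocols.

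The values used are whole-number counts per gene that the authors deposited in one table for all libraries, not normalized. Per the submitters' processing notes the tools were fastp, STAR 2.7.1a, featureCounts and DESeq2, with the hg38 genome; their roles, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, antisense and overlapping genes are uncertain, as are genes with near-identical copies. Of counts between 1 and 20, from 68.1% to 70.3% per library were even numbers, and whether a count stands for a read or a read pair is not stated. If mates were counted singly, the true number of fragments is lower than the counts, which the tests allow for only through the estimated spread; counts halved and rounded up were therefore tried as an added alternative. The table held 60625 gene lines. Of these, 3 were broken across lines and were left out (279 counts over all libraries), so that ANK2 was not analysed here, and 60622 were used, of which 23834 had 0 counts everywhere. No column belonged to a sample outside the series. Library totals ran from 33973861 to 41890528 counts. A count of 0 was given an upper limit of 3 counts. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

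Replicates of each group differed by more than the sampling noise of independent counts (chi-square per degree of freedom from 3.75 to 3.86 over genes). The counts may not be independent, as described above, so this ratio cannot tell technical repeats from separate cultures. Pearson's r between replicates was from 0.996 to 0.996 across genes on the log2 scale. The libraries were not identical, and none was treated as a duplicate. Library sizes were scaled by TMM, with factors from 0.957 to 1.06. Genes passing edgeR's filterByExpr by group (21066) were fitted in a single model of 4 groups with 4 residual degrees of freedom by edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. The contrasts were miR-375 against control in LNCaP, the same in PC3, and their difference (LNCaP effect minus PC3 effect, the interaction). Adjusted p-values are Benjamini-Hochberg over the tested genes, called under 0.05. SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. CPM values use TMM-scaled library sizes, except the upper limits for MIR375, which use library totals without TMM scaling. Tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold among 20051 genes, the fit recovered 72.0% and 89.0% of them in the LNCaP comparison, calling 10 unchanged genes, and 77.0% and 93.0% in the PC3 comparison, calling 12. The changed genes were drawn only from those over a set floor of mean CPM in the controls, so recovery at the lowest counts is not known.

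Before the data were examined, 33 gene lists were fixed, along with the tests, the alternatives and the rule for naming genes. Of these, 31 were tested with camera (limma 3.58.1, inter-gene correlation 0.01) in each line with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. The other 2, markers of each line, were used only to check the labels. With an estimated correlation p could rise even where the estimate was under 0.01, so that form of the test changes more than the correlation. The lists were miR-375 targets from earlier literature, androgen receptor targets, DNA replication and G1/S, mitosis and G2/M, p53 targets, the integrated stress response, endoplasmic reticulum chaperones and the unfolded protein response, cholesterol biosynthesis, fatty acid synthesis, hypoxia and glycolysis, interferon-stimulated genes, NF-kB and inflammatory cytokine genes, YAP/TAZ targets, mesenchymal, epithelial, luminal, basal and neuroendocrine genes, JAK-STAT3 targets, microRNA machinery, autophagy and lysosome, integrins and laminins, immediate early genes, cytosolic ribosomal proteins, mitochondrially encoded genes, the nuclear-encoded respiratory chain, replication-dependent histones, heat shock, and markers of fibroblasts, endothelium and leukocytes. Target lists were written from memory of the literature and not from these samples. Genes that overlap between lists count in each.

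Named genes followed the rule. For each line it took the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 CPM in the higher group and both miR-375 libraries on the same side of both controls. For changes shared by the lines it took 5 genes per direction, and for the interaction 5 per sign. It added all called literature targets, MIR375, and 2 to 4 members of each list by smallest p. A few genes that the rule gives are not reported here. A second set of 10 interaction genes, called in both lines, was chosen after the values were seen, because every gene that the rule gave was at 0 in a group. Genes named as the exceptions of a list (OAS2, OAS3, NUSAP1, CCNE1, ISG20) were also chosen after their values were seen.

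Overlap of calls between the lines was tested with Fisher's exact test against independent lists. The lines have separate controls. For seed sites, the longest 3′ UTR of each protein-coding gene in GENCODE 29 (GRCh38) was searched for CGAACAA, CGAACAAA and GAACAAA, the matches to the seed of miR-375-3p (UUUGUUCGUUCGGCUCGCGUGA). Genes with a site were compared with the other genes by camera, with Benjamini-Hochberg adjustment over 6 tests (3 site definitions in 2 lines), and 16047 7-mers found in at least 100 of 14895 UTRs were ranked by the shift of genes holding each, divided by its SE, in a regression on log10 UTR length (Python 3.11.15, numpy 2.4.6, scipy 1.17.1), after a planted 7-mer ranked 1st in simulated data. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, DESeq2 size factors, total-count scaling, no filter on low counts, a filter of 5 CPM in 2 libraries, each line fitted alone, the replicate number as a block, stricter thresholds, an estimated correlation for lists, other site definitions, and leaving out each library in turn. Halved counts and the fry test were added after the data were seen, as were list tests on the interaction, the GAACAAA ranking, the adjustment for GC content and the comparison of CGAACAA with GAACAAA alone. Figures were drawn with matplotlib 3.10.9.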

Results

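Gene expression was measured by poly(A) RNA-seq in LNCaP and PC3, human prostate cancer cell lines, with and without overexpression of miR-375, a microRNA that base-pairs with messenger RNAs through its seed region. LNCaP is an androgen-responsive line derived from a lymph node metastasis, and PC3 is a line derived from a bone metastasis. Each of the 4 groups (control and miR-375 in each line) held 2 libraries. The deposited table gave whole-number read counts per gene, with totals of 34072786 and 35689829 in the LNCaP controls and 34857651 and 33973861 in LNCaP with miR-375. The totals were 41890528 and 40245979 in the PC3 controls and 41662584 and 41728025 in PC3 with miR-375. The series asks which genes change with miR-375 in each line, and the design allows a further question, whether the change differs between the lines. Levels are given as CPM, counts scaled to a common library size with TMM, in the form mean ± SD of the 2 libraries of a group (n = 2). Changes are given as log2 fold changes of miR-375 over control ± SE. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 21066 tested genes, and a gene is said to have risen or fallen where that value was under 0.05. Gene lists were tested against all other genes with camera, adjusted over 31 lists in each line. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

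The gene of the manipulated microRNA, MIR375 (chromosome 2, 219001645 to 219001708, minus strand, GRCh38), had 0 counts in all 8 libraries. At a floor of 3 counts this allows up to 0.0883 CPM in the second LNCaP miR-375 library and up to 0.0720 CPM in the first PC3 miR-375 library. These limits cover counting error only and use library totals without TMM scaling, unlike the other CPM values. A poly(A) library does not capture a mature microRNA, so this row checks neither the labels nor the overexpression. Of 29 line markers fixed in advance, 26 were higher in the controls of the line they were listed for and 3 in those of the other line. The 3 were UCHL1 (7.50 ± 2.09 CPM in LNCaP and 0 in PC3) and LCN2 (24.4 ± 1.94 and 14.6 ± 3.32), listed for PC3, and PTPRN2, listed for LNCaP, with a log2 difference of 1.08 towards PC3. HOXB13, a prostate homeobox gene listed for LNCaP, differed little (607 ± 0.412 and 557 ± 3.50). KLK3, which encodes prostate-specific antigen, stood at 2786 ± 35.2 CPM in the LNCaP controls and had no counts in PC3. FOSL1, an AP-1 gene, stood at 0.931 ± 0.222 CPM in the LNCaP controls and 722 ± 6.24 in the PC3 controls. The first principal component carried 90.1% of the variance and separated the lines, and the next 2 carried 4.02% and 2.03%.

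In LNCaP, genes reported in earlier literature as miR-375 targets fell with miR-375, and so did nearly every gene of DNA replication and mitosis that was listed. MTDH, a metastasis-associated gene and a reported target, fell 2.80-fold, from 330 ± 2.72 to 118 ± 6.62 CPM. YAP1, the transcriptional effector of the Hippo pathway, fell 2.05-fold, from 123 ± 2.97 to 60.1 ± 2.96 CPM, and SEC23A, a coat protein of secretory vesicles, fell 2.47-fold, from 188 ± 2.46 to 76.2 ± 8.77 CPM. The replication licensing helicase gene MCM7 fell 2.51-fold, from 371 ± 1.23 to 147 ± 2.43 CPM, and the mitotic kinase gene CDK1 fell 2.55-fold, from 433 ± 19.6 to 170 ± 7.81 CPM. Of 37 interferon-stimulated genes 19 rose and 2 fell, with OASL up 4.63-fold and IFIT2 up 3.76-fold, and the list passed with the preset correlation but not with an estimated one (adjusted p = 0.0804 with an estimated correlation).

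Across all tested genes, 2927 rose and 3933 fell in LNCaP, 507 and 465 of them by at least 2-fold. The balance of these counts depended on scaling: with library sizes taken from total counts in place of TMM, 4719 rose and 2613 fell, because that scaling shifted the median log2 fold change by 0.12. Changes smaller than this shift had no settled direction in LNCaP.

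Of 32 tested literature targets, 23 fell and 1 rose in LNCaP, and the counts were the same when adjusted over the list alone. The median change was −0.55, and the list fell against all other genes (camera, adjusted p = 7.99e-11, and 0.0357 with an estimated correlation). Besides MTDH, SEC23A and YAP1, the genes that fell were C1QBP (−0.74), MTPN (−0.65), NCAPG2 (−0.88), CIP2A (−1.31), KLF5 (−1.19), SLC7A11 (−0.71), QKI (−0.66), CAV1 (−2.29), EIF4G3 (−0.44), LDHB (−1.77), FZD8 (−0.90), SP1 (−0.36), TIMM8A (−0.67), ERBB2 (−0.24), AIFM1 (−0.22), CCN2 (−1.63), PDPK1 (−0.28), IGF1R (−0.36), GPHN (−0.29) and CADM1 (−0.86). CBX7, a polycomb gene, rose by 0.41. CAV1 was a trace transcript in LNCaP, at 1.87 and 1.38 CPM in the first and second control and 0.434 and 0.222 CPM with miR-375. The calls of AIFM1, ERBB2, PDPK1, IGF1R, GPHN and CADM1 ended with total-count scaling (adjusted p from 0.0680 to 0.198). Without the first LNCaP control the calls of ERBB2 (0.0574), PDPK1 (0.0705) and IGF1R (0.139) ended, without the second that of GPHN (0.490), and without any of the 4 LNCaP libraries that of CADM1. The calls of CADM1 and GPHN also ended with DESeq2 (0.148 and 0.101) and without a filter on low counts (0.0530 and 0.0513), and that of GPHN with limma-voom (0.0692). IGF1R also lost its call without the first LNCaP miR-375 library (0.184), and PDPK1 (0.128) and GPHN (0.591) without the second. The call of CCN2, at 0.945 ± 0.202 CPM in the controls, ended without the second LNCaP miR-375 library (adjusted p = 0.0590), as did that of CBX7 (0.0541).

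All 34 tested genes of DNA replication and the G1/S transition fell in LNCaP, with a median change of −1.32 (adjusted p = 8.33e-43, and 0.00159 with an estimated correlation). MCM4 fell from 183 ± 1.75 to 61.0 ± 0.149 CPM, MCM3 from 125 ± 0.550 to 41.1 ± 3.22, and the ribonucleotide reductase subunit RRM2 from 181 ± 0.780 to 65.4 ± 3.45. Of 37 genes of mitosis and G2/M, 36 fell and none rose, with a median of −0.94 (adjusted p = 1.01e-38, and 0.00159 with an estimated correlation). The cytokinesis gene ANLN fell from 76.0 ± 1.46 to 26.9 ± 0.330 CPM, the proliferation marker MKI67 by 1.39 on the log2 scale and the survivin gene BIRC5 by 1.22, while NUSAP1 stood at 0.05 and did not pass. The list-alone adjustment gave the same counts for both groups.

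Of 37 interferon-stimulated genes, 19 rose and 2 fell in LNCaP (20 and 2 adjusted over the list alone), with a median of 0.41 (adjusted p = 3.08e-06, and 0.0804 with an estimated correlation). OASL, an antiviral gene, rose from 3.09 ± 0.159 to 14.3 ± 0.597 CPM, IFIT2 from 3.75 ± 0.516 to 14.1 ± 1.41, IFI44 from 2.94 ± 0.153 to 9.31 ± 0.169 and IFI6 from 8.94 ± 0.00645 to 20.4 ± 0.987. OAS2 fell by 1.31 and OAS3 by 0.41. Androgen receptor targets fell on balance, 15 lower and 6 higher of 30 (16 and 7 adjusted over the list alone). Their median was −0.35 (adjusted p = 5.81e-04, and 0.166 with an estimated correlation). KLK3 fell 1.52-fold, from 2786 ± 35.2 to 1829 ± 45.9 CPM, KLK2 1.95-fold, from 289 ± 3.29 to 148 ± 15.5, the transporter gene ABCC4 by 0.56 and the metalloreductase gene STEAP2 by 0.36. Luminal prostate genes share KLK3, KLK2 and STEAP2 with that list. Of 19, 11 fell and 4 rose (12 and 4 adjusted over the list alone), with a median of −0.14 (adjusted p = 0.00803, and 0.166 with an estimated correlation).

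Heat shock genes fell in LNCaP, 13 of 20 with 2 higher (14 and 2 adjusted over the list alone). Their median was −0.26 (adjusted p = 2.94e-05, and 0.166 with an estimated correlation), and the chaperone genes that fell included HSPD1 (−0.36), HSP90AA1 (−0.35) and DNAJB1 (−0.45). Among p53 targets 10 of 26 rose and 4 fell on both adjustments, over all genes and adjusted over the list alone. The median was 0.17 (adjusted p = 0.00803, and 0.323 with an estimated correlation). The cell cycle inhibitor gene CDKN1A rose from 213 ± 6.97 to 299.9 ± 25.9 CPM and TP53I3 from 3.48 ± 0.0966 to 9.18 ± 0.565. Autophagy and lysosome genes had 12 of 31 higher and 4 lower (15 and 5 adjusted over the list alone; median 0.09, adjusted p = 0.00914, and 0.165 with an estimated correlation). CTSB, a lysosomal protease gene, rose by 0.67. Fatty acid genes had 9 of 20 lower and 2 higher on both adjustments (median −0.05, adjusted p = 0.00867, and 0.165 with an estimated correlation). The acyl-CoA synthetase gene ACSL3 fell from 225 ± 0.742 to 83.2 ± 5.40 CPM and FASN, the fatty acid synthase gene, by 0.54. MicroRNA machinery genes had 9 of 22 lower and 3 higher (12 and 3 adjusted over the list alone; median −0.17, adjusted p = 0.0138, and 0.323 with an estimated correlation). The argonaute gene AGO2 fell by 0.39 and TNRC6A, which binds argonaute proteins, by 0.52.

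Small shifts passed the list test in LNCaP for 5 further groups. Cytosolic ribosomal proteins had 31 of 50 lower and 0 higher (35 and 0 adjusted over the list alone; median −0.10, adjusted p = 7.14e-06, and 0.553 with an estimated correlation), RPL4 falling by 0.31. Nuclear-encoded respiratory chain genes had 16 of 36 lower and 5 higher on both adjustments (median −0.13, adjusted p = 0.00537, and 0.445 with an estimated correlation), NDUFA4 falling by 0.53. Chaperones and unfolded protein response genes of the endoplasmic reticulum had 10 of 23 lower and 2 higher (10 and 3 adjusted over the list alone; median −0.09, adjusted p = 0.0214, and 0.193 with an estimated correlation), PDIA4 falling by 0.87. Mitochondrially encoded genes had 5 of 13 higher and 0 lower on both adjustments (median 0.08, adjusted p = 0.0138, and 0.604 with an estimated correlation), and replication-dependent histone genes 6 of 21 higher and 1 lower on both (median 0.27, adjusted p = 0.0421, and 0.323 with an estimated correlation). With total-count scaling the medians of the ribosomal protein (0.02), endoplasmic reticulum (0.03) and fatty acid (0.07) groups turned positive without a call, and the respiratory chain, luminal, microRNA machinery and histone groups also lost theirs. The histone call ended when any single library other than the first LNCaP control was left out (adjusted p from 0.0828 to 0.588), and its median turned to −0.14 without the second LNCaP control and to −0.08 without the first LNCaP miR-375 library. Whichever PC3 library was left out, the histone median in LNCaP was 0.03. Those fits ran the low-count filter again, so the genes tested changed, and the shift cannot be laid to a given PC3 library. With replicate number as a block the histone call ended as well (adjusted p = 0.0685). Leaving out single LNCaP libraries ended the calls of the endoplasmic reticulum group (any of the 4), the ribosomal and respiratory groups (the first control, adjusted p = 0.161 and 0.162, with medians of −0.01 and −0.06), the microRNA machinery (the second control, 0.0959) and the fatty acid group (the first miR-375 library, 0.0532). With LNCaP fitted alone the calls of the respiratory chain (0.0502), endoplasmic reticulum (0.0685) and microRNA machinery (0.101) groups ended.

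The other 15 tested lists did not pass in LNCaP. The integrated stress response (5 higher and 11 lower of 24, adjusted p = 0.0855) still held PSAT1, a serine synthesis gene that fell by 1.45. Counts of higher and lower genes were 6 and 6 of 25 for cholesterol biosynthesis (adjusted p = 0.829), 9 and 9 of 28 for hypoxia and glycolysis (0.703), 8 and 3 of 30 for NF-kB and inflammatory cytokine genes (0.397), 9 and 9 of 23 for YAP/TAZ targets (0.660), 10 and 6 of 29 for mesenchymal genes (0.613) and 10 and 6 of 30 for epithelial genes (0.703). They were 6 and 4 of 20 for basal prostate genes (0.829), 5 and 5 of 18 for neuroendocrine genes (0.961), 6 and 7 of 24 for JAK-STAT3 targets (0.852), 8 and 5 of 30 for integrins and laminins (0.613) and 5 and 6 of 24 for immediate early genes (0.703). Markers of other cell types did not pass either, with 2 and 0 of 11 for fibroblasts (0.716), 1 and 1 of 9 for endothelium (0.703) and 0 and 0 of 7 for leukocytes (0.257). The integrated stress response passed without the second LNCaP control (adjusted p = 0.0439), and hypoxia without the second LNCaP miR-375 library (0.0420). MYC, on both the JAK-STAT3 and the immediate early list, fell from 349 ± 7.43 to 185 ± 2.77 CPM, and HK2, a glycolytic enzyme gene, fell by 0.89. With adjustment over the list alone the counts of higher and lower genes became 11 and 9 for hypoxia, 10 and 9 for YAP/TAZ targets, 10 and 7 for epithelial genes, 5 and 6 for neuroendocrine genes and 7 and 7 for JAK-STAT3 targets, and they did not change for the other 10. The camera direction was up against a negative median and mean for YAP/TAZ targets (−0.04 and −0.35) and JAK-STAT3 targets (−0.04 and −0.12). Median and mean differed in sign for NF-kB (0.07 and −0.03), mesenchymal (0.09 and −0.23), epithelial (0.05 and −0.13), basal (−0.04 and 0.26) and neuroendocrine genes (−0.10 and 0.44). So they did for markers of fibroblasts (0.07 and −0.06) and endothelium (0.24 and −0.01).

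The genes with the largest rises in LNCaP, at 5 CPM or more, were SYP, a synaptic vesicle gene that rose 5.41-fold from 1.07 ± 0.105 to 5.82 ± 1.21 CPM, OASL, CLEC7A (2.00), ARG1 (1.95), IFIT3 (1.95), IFIT2, STMN4 (1.91), RAB37 (1.87), C1QTNF6 (1.80) and IFI44 (1.66). CLEC7A and STMN4 did not pass with DESeq2 (adjusted p = 0.159 and 0.253). The largest falls were of TBXT, the brachyury gene, from 6.48 ± 2.55 to 0.192 ± 0.0358 CPM (−5.05 ± 0.45), UCHL1, a ubiquitin hydrolase gene, from 7.50 ± 2.09 to 0.358 ± 0.199, TGFBI, a matrix protein gene, from 9.57 ± 2.19 to 0.739 ± 0.105, LGALS3, the galectin-3 gene, from 9.87 ± 4.85 to 0.833 ± 0.278, and AKR1B10, an aldo-keto reductase gene, from 5.78 ± 2.34 to 0.850 ± 0.129. These 5 genes also differed between the 2 LNCaP controls, with 13.3 and 6.45 CPM for LGALS3, and the LGALS3 call (adjusted p = 0.0125) ended without either miR-375 library (0.0674 and 0.0803). The next were the replication genes CDC6 (4.16-fold, from 69.7 ± 1.18 to 16.7 ± 0.502 CPM), MCM10 and CLSPN, the DNA methylation maintenance gene UHRF1 and the amino acid transporter gene SLC6A19, with changes from −2.06 to −1.91.

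In PC3, literature targets and genes of replication and mitosis fell, and interferon-stimulated and inflammatory genes rose. YAP1 fell 2.88-fold, from 171 ± 6.16 to 59.4 ± 1.84 CPM, MTDH 2.12-fold, from 449 ± 0.644 to 212 ± 4.20, and QKI, an RNA-binding protein gene, 3.25-fold, from 225 ± 8.79 to 69.4 ± 5.79. ANLN fell 4.46-fold, from 263 ± 1.28 to 59.0 ± 4.52 CPM. PTGS2, the inducible cyclooxygenase gene, rose 15.0-fold from 20.5 ± 0.690 to 307 ± 7.81 CPM, the complement gene C3 rose 22.0-fold from 8.19 ± 0.638 to 180 ± 5.95, and FGB, a fibrinogen chain gene, rose 159-fold from 0.458 ± 0.0126 to 73.5 ± 0.157. PLAT, the tissue plasminogen activator gene, fell 11.1-fold, from 1274 ± 12.5 to 115 ± 2.74 CPM.

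Across all tested genes, 4679 rose and 4380 fell in PC3, 1458 and 768 of them by at least 2-fold. This balance too depended on the processing, with 5672 higher and 3602 lower under total-count scaling and 3721 higher and 3954 lower with DESeq2. The genes that fell were also the more numerous without a filter on low counts (4230 and 4567) and with PC3 fitted alone (4486 and 4777). So they were without the second PC3 control and without any single LNCaP library. Leaving out a library also changed the genes tested, since the low-count filter was run again, so these turns cannot be laid to given libraries. Of the 32 literature targets 23 fell and 1 rose (23 and 2 adjusted over the list alone), with a median of −0.54 (adjusted p = 5.65e-10, and 0.0305 with an estimated correlation). Besides YAP1, MTDH and QKI, the genes that fell were CAV1 (−0.96), MTPN (−0.79), C1QBP (−0.84), SEC23A (−0.99), TNS3 (−0.83), CIP2A (−1.43), CCN2 (−1.43), NCAPG2 (−0.94), FZD8 (−0.49), SLC7A11 (−0.63), ATG7 (−0.67), EIF4G3 (−0.49), JAK2 (−0.77), AIFM1 (−0.33), PIK3CA (−0.37), RASD1 (−0.58), TIMM8A (−0.38), SP1 (−0.17) and GPHN (−0.20). LDHB fell from 3.84 ± 0.376 to 0.476 ± 0.0685 CPM, and IGF1R rose by 0.53. The calls of SP1 and GPHN ended with total-count scaling (adjusted p = 0.127 and 0.218), and that of GPHN with DESeq2 (0.120), with a filter of 5 CPM (0.0748) and without the second control or the first miR-375 library (0.295 and 0.354).

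Replication genes fell in 33 of 34 cases in PC3 (median −1.21, adjusted p = 4.97e-28, and 0.00317 with an estimated correlation), CCNE1 (0.17) being the one that did not pass. MCM3 fell from 149 ± 0.00667 to 53.1 ± 0.676 CPM and MCM5 3.61-fold, from 78.5 ± 0.921 to 21.7 ± 1.66. Mitosis genes fell in 36 of 37 cases (median −1.18, adjusted p = 5.07e-34, and 0.00317 with an estimated correlation), with CDK1 falling 2.53-fold, BIRC5 by 1.40 and the topoisomerase gene TOP2A by 1.40. None rose on either list, and the counts were the same adjusted over the list alone.

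Interferon-stimulated genes rose in 32 of 37 cases with 1 lower, on both adjustments, over all genes and adjusted over the list alone (median 0.59, adjusted p = 9.25e-15, and 0.0160 with an estimated correlation). IFI6 rose 4.01-fold, from 313 ± 9.33 to 1255 ± 51.1 CPM, the tetherin gene BST2 8.55-fold, from 21.6 ± 0.811 to 185 ± 0.950, and ISG15 from 311 ± 0.837 to 659 ± 10.6, while ISG20 fell by 1.17. NF-kB and inflammatory cytokine genes rose in 21 of 30 cases with 1 lower (24 and 2 adjusted over the list alone). Their median was 0.71 (adjusted p = 2.63e-09, and 0.0301 with an estimated correlation). Besides PTGS2, the neutrophil chemokine genes CXCL8 and CXCL6 rose by 1.27 and 1.28, CXCL8 from 303 ± 1.88 to 729 ± 0.395 CPM, and LIF, a cytokine gene, fell from 516 ± 2.19 to 264 ± 2.96. Hypoxia and glycolysis genes had 17 of 28 higher and 6 lower (18 and 6 adjusted over the list alone; median 0.33, adjusted p = 2.84e-04, and 0.459 with an estimated correlation). The secreted lipase inhibitor gene ANGPTL4 rose 12.7-fold, from 17.1 ± 0.914 to 217 ± 8.80 CPM, and the vasodilator gene ADM rose by 2.03. Replication-dependent histone genes had 12 of 21 higher and 1 lower on both adjustments (median 1.00, adjusted p = 7.63e-05, and 0.0856 with an estimated correlation). H1-2 rose 3.59-fold, from 45.2 ± 0.995 to 163 ± 0.287 CPM. Histone genes have near-identical copies, so counts of single members are uncertain.

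Basal prostate genes fell in PC3, 12 of 20 with 4 higher on both adjustments (median −0.60, adjusted p = 2.84e-04, and 0.0656 with an estimated correlation). The laminin receptor gene ITGA6 fell 2.84-fold, from 632 ± 6.65 to 223 ± 4.77 CPM, and LAMB3 fell from 774 ± 22.6 to 396 ± 7.60. YAP/TAZ targets had 12 of 23 lower and 5 higher on both adjustments (median −0.29, adjusted p = 0.00385, and 0.0908 with an estimated correlation). The receptor tyrosine kinase gene AXL fell from 342 ± 9.89 to 171 ± 0.443 CPM, NT5E by 0.99 and CCN2 by 1.43, whereas IGFBP3 rose by 1.47. Epithelial genes had 15 of 30 higher and 5 lower on both adjustments (median 0.43, adjusted p = 0.0294, and 0.156 with an estimated correlation). CDH1, the E-cadherin gene, rose 4.27-fold from 3.85 ± 0.488 to 16.5 ± 1.82 CPM and SPINT1 by 1.16, but the more abundant CLDN4 fell from 854 ± 5.68 to 345 ± 9.85 and MAL2 fell by 1.10. With PC3 fitted alone the camera direction of the epithelial list was down (median 0.30, adjusted p = 0.831).

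Mitochondrially encoded genes fell in PC3, 12 of 13 (13 adjusted over the list alone) with none higher (median −0.41, adjusted p = 3.49e-08, and 0.290 with an estimated correlation). MT-ATP8 fell 2.05-fold and MT-CO3 from 1934 ± 16.0 to 1315 ± 9.35 CPM. Nuclear-encoded respiratory chain genes had 19 of 36 lower and 4 higher on both adjustments (median −0.10, adjusted p = 0.0104, and 0.459 with an estimated correlation), COX7C falling by 0.61. Androgen receptor targets had 14 of 30 higher and 5 lower on both adjustments (median 0.15, adjusted p = 0.0410, and 0.355 with an estimated correlation). NDRG1 rose from 1241 ± 28.6 to 2459 ± 1.22 CPM and FOLH1, the prostate-specific membrane antigen gene, 15.8-fold from 0.358 ± 0.154 to 5.69 ± 0.338. Integrated stress response genes had 14 of 24 higher and 5 lower on both adjustments (median 0.23, adjusted p = 0.0484, and 0.423 with an estimated correlation). Those that rose included STC2 (1.24), DDIT4 (1.70) and the amino acid transporter gene SLC7A5 (1.22). Ribosomal protein genes had 27 of 50 lower and 11 higher (28 and 12 adjusted over the list alone; median −0.09, adjusted p = 0.0452, and 0.818 with an estimated correlation). Heat shock genes had 10 of 20 lower and 4 higher on both adjustments (median −0.07, adjusted p = 0.0452, and 0.423 with an estimated correlation), with the co-chaperone gene BAG3 falling by 1.20. Endothelial markers had 5 of 9 lower and 1 higher (6 and 1 adjusted over the list alone; median −0.71, adjusted p = 0.0452, and 0.355 with an estimated correlation). KDR, a growth factor receptor gene that PC3 itself expressed, fell from 322 ± 1.20 to 173 ± 0.364. The ribosomal and respiratory groups lost their calls with total-count scaling, and the heat shock median turned to 0.01 without a call. Leaving out single libraries ended the calls of the stress response list (any of the 8), androgen receptor targets (either PC3 control or the first PC3 miR-375 library), endothelial markers (either control or the second miR-375 library) and heat shock genes (the second control or the second miR-375 library). Those fits ran the low-count filter again, so the genes tested changed as well. Whichever LNCaP library was left out, the stress response median in PC3 was 0.20 to 0.21. The loss of that call there cannot be laid to a given LNCaP library. With replicate number as a block the calls of the stress response list (0.0566), androgen receptor targets (0.0647) and heat shock genes (0.0739) ended, and with PC3 fitted alone those of the respiratory chain (0.0507) and ribosomal proteins (0.0946).

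The other 14 lists did not pass in PC3. Counts of higher and lower genes were 10 and 7 of 26 for p53 targets (adjusted p = 0.786), 11 and 4 of 23 for the endoplasmic reticulum group (0.227), 16 and 7 of 31 for autophagy and lysosome genes (0.0578), 9 and 8 of 25 for cholesterol biosynthesis (0.938) and 6 and 7 of 20 for fatty acid genes (0.938). With total-count scaling the endoplasmic reticulum and autophagy groups passed (0.0444 and 0.0300). They were 12 and 10 of 29 for mesenchymal genes (0.941), 7 and 6 of 19 for luminal genes (0.481), 6 and 5 of 18 for neuroendocrine genes (0.938), 11 and 10 of 24 for JAK-STAT3 targets (0.786), 7 and 8 of 22 for microRNA machinery (0.956), 15 and 10 of 30 for integrins and laminins (0.759) and 9 and 8 of 24 for immediate early genes (0.811). Fibroblast markers had 4 and 2 of 11 (0.389), COL1A1 rising from 139 ± 4.03 to 373 ± 15.7 CPM, and leukocyte markers 1 and 0 of 7 (0.566). Single genes of these lists rose: the stress-induced cytokine gene GDF15 from 35.7 ± 2.10 to 125 ± 3.59 CPM, the pioneer factor gene FOXA1 by 1.36 and the matrix gene THBS1 5.85-fold to 209 ± 2.56. Among mesenchymal genes the AP-1 gene FOSL1 fell from 722 ± 6.24 to 294 ± 1.94, and among fatty acid genes ACSL3 fell by 1.42. With adjustment over the list alone the counts became 10 and 8 for p53 targets, 16 and 8 for autophagy, 9 and 9 for cholesterol, 9 and 7 for fatty acid and 13 and 10 for mesenchymal genes. They became 8 and 8 for microRNA machinery, 16 and 11 for integrins and laminins and 0 and 0 for leukocyte markers, and they did not change for the other 6. The camera direction went against the median for cholesterol biosynthesis (−0.08, mean 0.04) and microRNA machinery (0.07, mean −0.02), and against median and mean for immediate early genes (0.14 and 0.25). Median and mean differed in sign for p53 targets (0.06 and −0.03) and mesenchymal genes (0.00 and −0.06).

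The largest rises in PC3, at 5 CPM or more, were of FGB, CP (the ceruloplasmin gene, from 0.749 ± 0.105 to 102 ± 1.12 CPM), C3, FOLH1, the growth factor gene BMP2 (from 0.914 ± 0.191 to 14.5 ± 2.30), PTGS2, the sonic hedgehog gene SHH (from 2.97 ± 0.208 to 38.0 ± 1.23), ANGPTL4, CYP1B1 (3.62) and FGF7 (3.58). After PLAT, the largest falls were of CTSW (−2.91), TFF2 (−2.81), ESM1 (from 81.4 ± 2.02 to 11.6 ± 0.810 CPM), GABBR2 (−2.74), TNS1 (−2.47), FGF1 (−2.45), SH3PXD2A-AS1 (−2.22), the centriole gene POC1B (−2.17) and ANLN (−2.16). SH3PXD2A-AS1 is an antisense gene, and without a stated strand setting its reads cannot be told apart from those of its partner gene.

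**Figure D1:**
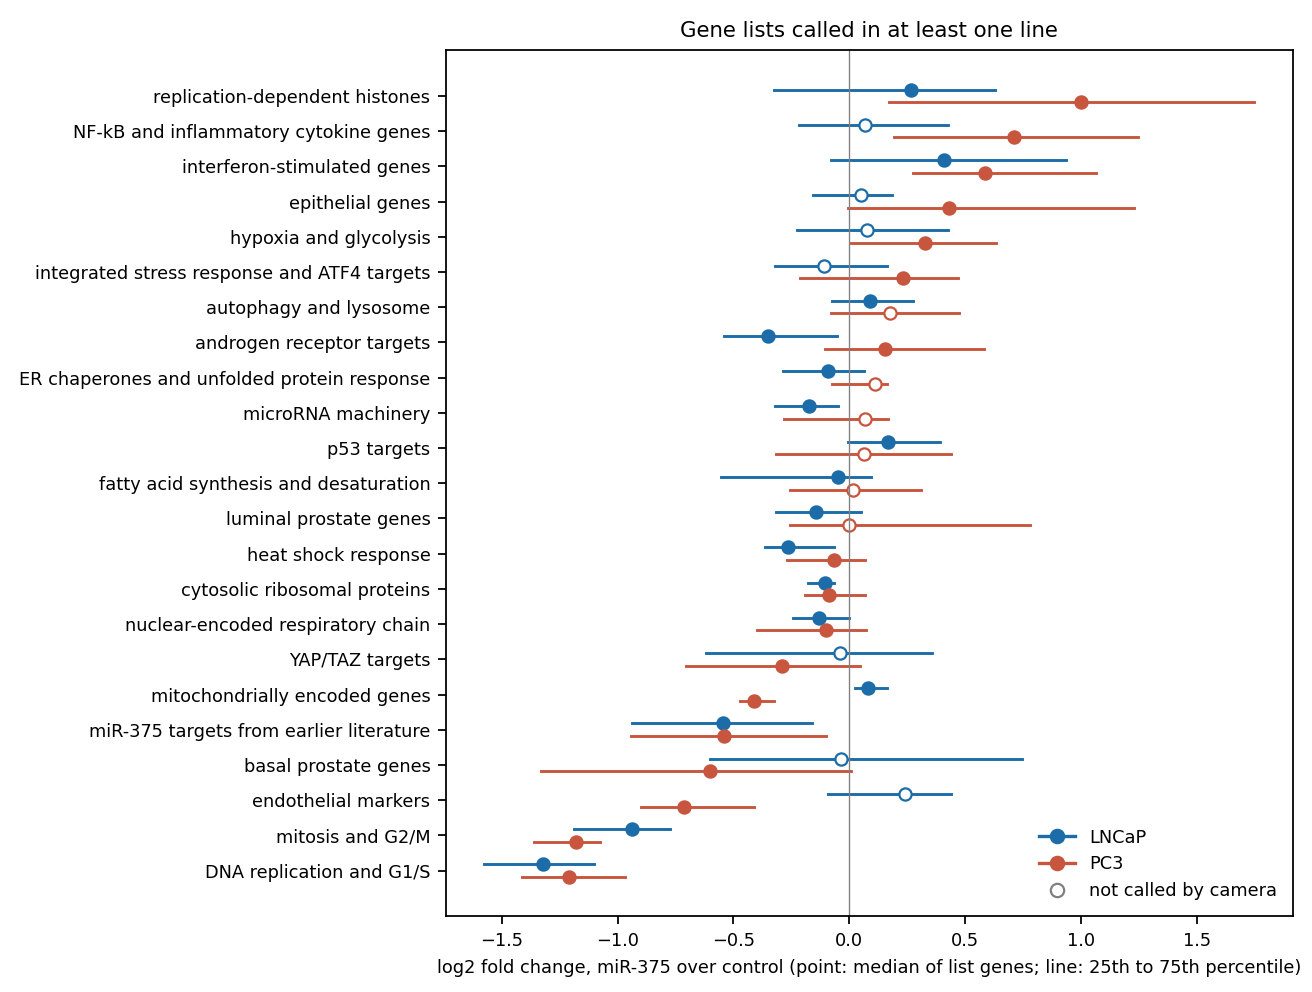
Median log2 fold change of miR-375 over control for each gene list that passed camera in at least 1 line, with a line from the 25th to the 75th percentile of its genes, LNCaP in blue and PC3 in red, open points where the list did not pass. Replication (−1.32 and −1.21), mitosis (−0.94 and −1.18) and literature targets (−0.55 and −0.54) lie to the left in both lines, while the median of androgen receptor targets lies at −0.35 in LNCaP and 0.15 in PC3. With total-count scaling the LNCaP medians of the ribosomal protein, endoplasmic reticulum and fatty acid lists and the PC3 median of the heat shock list turned positive, as did the LNCaP medians of YAP/TAZ targets (−0.04 to 0.08), basal genes (−0.04 to 0.09) and the integrated stress response (−0.11 to 0.01), which had not passed in LNCaP.

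Calls in the 2 lines overlapped. CDC6, which loads the replicative helicase, fell from 69.7 ± 1.18 to 16.7 ± 0.502 CPM in LNCaP and from 49.7 ± 0.955 to 13.5 ± 1.14 in PC3. The thymidylate synthase gene TYMS fell by 1.80 and 1.69, MCM5 by 1.78 and 1.85 and POC1B by 1.74 and 2.17. CAMK2N1, an inhibitor of a calcium-dependent kinase, rose from 304 ± 19.9 to 789 ± 16.8 CPM in LNCaP and from 5.28 ± 1.05 to 14.6 ± 0.164 in PC3, and TMEM229B rose by 1.59 and 2.14, the glycogen regulator gene PPP1R3B by 1.31 and 1.39 and FBXO2 by 1.26 and 1.27. ZNF702P also rose (1.22 and 1.24), but it is a pseudogene whose reads may be shared with related zinc finger genes. In all, 1495 genes rose in both lines, where independent lists of these sizes would share 650 (odds ratio 4.90), and 2215 fell in both, where independent lists would share 818 (odds ratio 8.91). Both odds ratios had p at or under 1e-300 by Fisher's exact test, two-sided, although genes are not independent replicates. The tested genes also included some near 0 in a line, which could hardly be called there, so the expected numbers and odds ratios are rough. Opposite calls were fewer than independent lists would give, 365 higher in LNCaP and lower in PC3 against 609, and 541 lower in LNCaP and higher in PC3 against 874 (Fisher's exact test, p = 3.48e-36 and 2.94e-49). Of 4616 genes called in both lines 80.4% had the same direction. Across genes, which are not independent replicates, the log2 fold changes of the 2 lines had Pearson's r = 0.138 over all tested genes and 0.373 over those called in both.

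**Figure D2:**
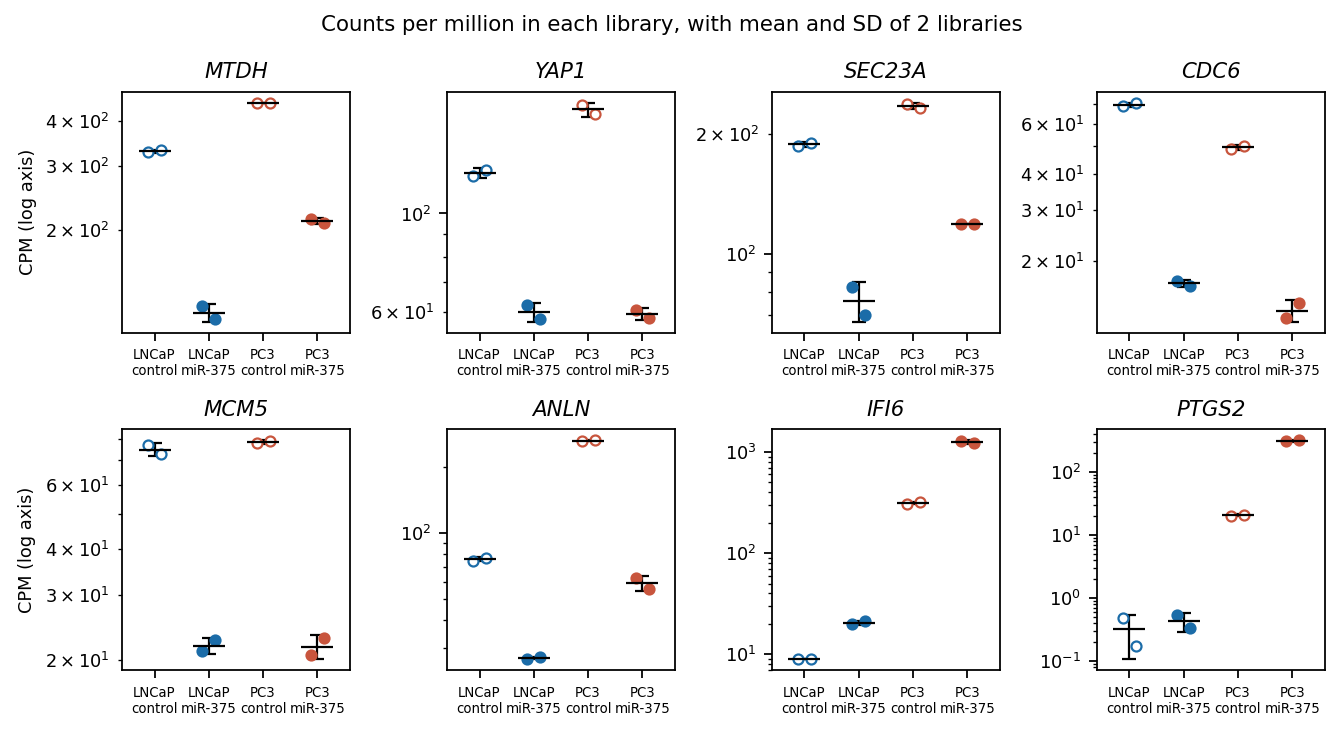
CPM on log axes for 8 named genes in each of the 8 libraries (open points, control; filled points, miR-375; LNCaP in blue, PC3 in red), with the mean and SD of each group of 2. In both lines MTDH, YAP1, SEC23A, CDC6, MCM5 and ANLN were lower and IFI6 was higher in both miR-375 libraries than in both controls, while PTGS2 rose from 20.5 to 307 CPM in PC3 and stayed under 1 CPM in LNCaP.

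The change with miR-375 differed between the lines for 5589 genes by the interaction test, 2303 with a higher value in LNCaP and 3286 with a higher value in PC3, 477 and 837 of them by at least 2-fold. The balance was even with DESeq2 (2264 and 2263) and with its size factors (2735 and 2740). It turned without a filter on low counts (3097 and 2353) and with halved counts, a test chosen after the data were seen (3032 and 2572). It also turned without any single LNCaP library, but the low-count filter was then run again and the genes tested changed. FAM43A rose in LNCaP from 63.9 ± 1.44 to 87.8 ± 0.264 CPM and fell in PC3 from 453 ± 2.93 to 136 ± 2.96, a difference of 2.19 ± 0.06 on the log2 scale. The metalloprotease gene TLL1 fell in LNCaP from 137 ± 6.74 to 86.8 ± 0.0807 CPM and rose in PC3 from 9.41 ± 0.136 to 58.5 ± 2.96, a difference of −3.29 ± 0.09, and TMEM45B fell from 62.7 ± 3.03 to 37.3 ± 0.0219 and rose from 25.1 ± 0.496 to 144 ± 0.475, a difference of −3.28 ± 0.08. These 3 genes belong to a set of 10 called in both lines that was chosen after the values were seen. The 10 genes given by the naming rule were all at 0 counts in a group, so that their fitted differences depend on the prior count and are no bounds. They were AREG, TFF2, CST4, LINC01605 and FBXO27, at 0 in the LNCaP controls and between 0.0554 and 0.534 CPM in LNCaP with miR-375, IL6, ABCC3, IFI16 and TFPI2, at 0 in LNCaP with miR-375, and UCHL1, at 0 in the PC3 controls. The adjusted p of TFF2 rose from 0.00993 to 1.00 without the second LNCaP miR-375 library, and that of TFPI2 from 0.00236 to 0.0851 and 0.0871 without either PC3 control. Among literature targets 7 had a higher and 9 a lower change in LNCaP by this test, and the list as a whole did not differ (median difference −0.02, adjusted p = 0.780).

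Messenger RNAs with a match to the miR-375 seed in the 3′ UTR were compared with those without. Matches were CGAACAA, CGAACAAA, which adds an A, and GAACAAA, which lacks the first base. The main comparison, of 170 genes with CGAACAA in the longest annotated 3′ UTR of GENCODE 29 against 14725 others, did not pass in either line. The difference in median log2 fold change was −0.0820 in LNCaP (camera over genes, n = 170, p = 0.0870, adjusted p = 0.127 over 6 tests) and −0.0126 in PC3 (p = 0.247, adjusted p = 0.247). By the standardized shift of genes holding it (shift divided by its SE), CGAACAA ranked 3630th in LNCaP and 4862nd in PC3 among 16047 7-mers with adjustment for UTR length, and 2099th and 3829th with length and GC content. Among the 105 7-mers of its base composition it ranked 10th and 17th with length and 11th and 17th with both. These ranks depend on the number of genes as well as on the shift, which was −0.08 in LNCaP (95% interval −0.212 to 0.0511) and −0.03 in PC3 (−0.176 to 0.108) with adjustment for length. The 2531 genes with any of the 3 matches differed from 12364 others by −0.112 in LNCaP (p = 0.00229, adjusted p = 0.0137) and −0.0861 in PC3 (p = 0.0217, adjusted p = 0.0651), with p = 0.0699 and 0.138 with an estimated correlation. The genes with CGAACAAA (n = 71) differed by −0.0893 in LNCaP (p = 0.106, adjusted p = 0.127) and −0.0718 in PC3 (p = 0.0366, adjusted p = 0.0732). GAACAAA, held by 2455 genes, ranked first in LNCaP and 11th in PC3 with adjustment for UTR length, and first in both lines with adjustment for length and GC content. Genes with CGAACAA were not told apart from the 2361 genes with GAACAAA alone, the difference adjusted for length being 0.05 in LNCaP (95% interval −0.0894 to 0.180) and 0.07 in PC3 (−0.0785 to 0.213). This comparison, the GAACAAA ranking and the GC adjustment were chosen after the medians of the site types were seen.

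**Figure D3:**
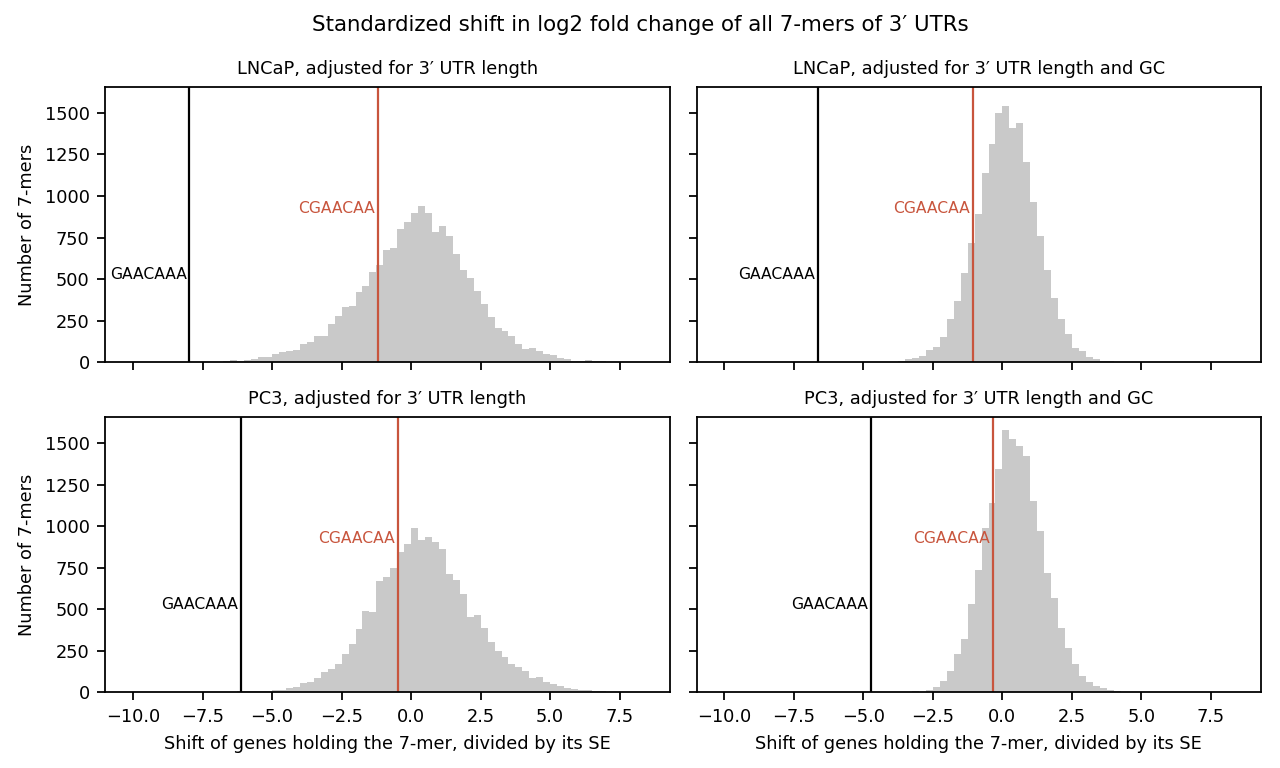
Distribution of the standardized shift in log2 fold change (shift divided by its SE, horizontal axis) over 16047 7-mers (number per bin, vertical axis) of genes that hold each 7-mer in the 3′ UTR, for each line and each adjustment. GAACAAA lies at −7.97 in LNCaP and −6.12 in PC3 with adjustment for length and at −6.63 and −4.74 with length and GC content, while CGAACAA lies between −1.20 and −0.334.

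Site positions are given for GRCh38, the build of the authors' alignment being hg38 per the submitters' processing notes. The 3′ UTR of MTDH (ENSG00000147649, gene at chromosome 8, 97644179 to 97728770, plus strand) holds CGAACAAA at 97726124 to 97726131, at UTR position 1454 of 4100, in the context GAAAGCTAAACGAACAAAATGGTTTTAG. YAP1 (chromosome 11, 102110461 to 102233423, plus strand) holds GAACAAA at 102230048 to 102230054 and at 102231623 to 102231629, SEC23A (chromosome 14, 39031919 to 39109646, minus strand) holds it at 39033045 to 39033051 and MTPN (chromosome 7, 135926761 to 135977353, minus strand) at 135926785 to 135926791, all in the 3′ UTR. QKI holds GAACAAA at 4 positions, the first at chromosome 6, 163571623 to 163571629, and POC1B at 4 positions, the first at chromosome 12, 89421103 to 89421109. CDC6 (chromosome 17, 40287633 to 40304657, plus strand) and MCM5 hold none of the 3 matches in the annotated 3′ UTR. Among genes named without a site search, PTGS2 lies on chromosome 1 at 186671791 to 186680427 (minus strand), PLAT on chromosome 8 at 42175233 to 42207724 (minus strand), FGB on chromosome 4 at 154562956 to 154571086 (plus strand) and ANLN on chromosome 7 at 36389806 to 36453791 (plus strand). Of the 32 tested literature targets 4 hold CGAACAA, 21 hold GAACAAA alone and 7 hold neither. Among the 4 with CGAACAA, MTDH fell in both lines, ATG7 fell in PC3 alone, and PTPN4 and SHOX2 fell in neither. The targets with any of these sites had 20 members lower and 0 higher in LNCaP and 18 lower and 1 higher in PC3 (medians −0.66 and −0.63), and those without one had 3 lower and 1 higher in LNCaP and 5 lower and 0 higher in PC3 (medians −0.03 and −0.37).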

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

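The S phase test and both tests of genes lost in LNCaP were chosen after the result was seen, as were the list tests on the interaction, the 10 interaction genes called in both lines, the GAACAAA ranking, the ranks by the shift itself and the comparison of CGAACAA with GAACAAA alone.

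The test of the difference between the lines (LNCaP effect minus PC3 effect) called 5589 genes, and 906 genes were called in both lines in opposite directions. Among the genes given by the naming rule the fitted differences were 6.98 for AREG, 6.95 for TFF2, 6.91 for CST4, 6.87 for LINC01605 and 6.55 for FBXO27, each with 0 counts in the LNCaP controls. On the other side they were −9.59 for UCHL1, with 0 counts in the PC3 controls, and −9.02 for TFPI2, −8.88 for IL6, −8.49 for ABCC3 and −8.34 for IFI16, with 0 counts in LNCaP with miR-375. These values depend on the prior count and are no bounds. IL6 stood at 0.414 CPM in the LNCaP controls and rose from 2.99 to 11.2 CPM in PC3. Without the second LNCaP miR-375 library the difference of TFF2 was 2.83 (adjusted p = 1.00), and the call of TFPI2 ended without either PC3 control (adjusted p = 0.0851 and 0.0871).

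Among genes called in both lines the differences were 2.23 for AOX1, 2.19 for FAM43A, 1.95 for KITLG, 1.95 for INHBB and 1.92 for LAMB3, which were higher with miR-375 in LNCaP and lower in PC3. They were −3.84 for FOLH1, higher in both lines, and −3.65 for S100P, −3.29 for TLL1, −3.28 for TMEM45B and −3.24 for ID3, which were lower with miR-375 in LNCaP and higher in PC3. The LNCaP call of ID3 ended with total-count scaling (adjusted p = 0.146), without the first LNCaP control (0.372) and without the second LNCaP miR-375 library (0.0539).

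For lists, the median difference was −0.55 for androgen receptor targets, 0.20 for mitosis, −0.28 for the integrated stress response, −0.22 for the endoplasmic reticulum group and −0.18 for hypoxia. It was −0.63 for NF-kB and inflammatory cytokine genes, −0.49 for epithelial genes, 0.53 for mitochondrially encoded genes and −0.75 for replication-dependent histones. These 9 passed camera with the preset correlation, with adjusted p from 7.37e-15 to 0.00701, and none passed with an estimated correlation (adjusted p from 0.142 to 0.538).

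Replication-dependent histone genes, which mostly lack a poly(A) tail, were higher with miR-375 in PC3 in 12 of 21 cases with 1 lower and 8 not called (median 1.00, adjusted p = 7.63e-05, and 0.0856 with an estimated correlation), while the call of the LNCaP median of 0.27 ended without any single library other than the first LNCaP control (adjusted p from 0.0828 to 0.588). More cells in S phase would raise replication genes, but the median of that list was −1.21 in PC3 (95% interval −1.39 to −1.09) and −1.32 in LNCaP (−1.48 to −1.21), which argues against it. Less strict poly(A) selection in the miR-375 libraries would raise other RNAs without a tail. The 4 such RNAs that could be tested (RN7SL1, SNORA73B, SNORD17 and VTRNA1-2) had a median of 0.32 in PC3 (95% interval −0.962 to 0.852) against 0.50, which is 0.5 times the histone median. In LNCaP their median was 0.22 (−0.836 to 0.778) against 0.13. None was called in either line, so the RNAs were too few to decide. Poly(A) selection and an effect of miR-375 on histone transcripts, which was not tested, both stay open and cannot be told apart here. Other causes were not tested.

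Genes with any of the 3 seed matches in the 3′ UTR, most of them with GAACAAA, were lower with miR-375 in LNCaP (adjusted p = 0.0137) and did not pass in PC3 (adjusted p = 0.0651), and with an estimated correlation they passed in neither line (p = 0.0699 and 0.138 by camera, n = 2531 genes). A linear effect of log10 UTR length and GC content is argued against as the whole cause. The shift of genes with any of the 3 matches adjusted for both was −0.10 in PC3 (95% interval −0.146 to −0.0599) and −0.14 in LNCaP (−0.181 to −0.102). These intervals treat genes as independent, which they are not, so length and GC content cannot be excluded. That any A-rich 7-mer of the same base composition gives such a shift is argued against by rank 1 of GAACAAA among 42 such 7-mers in each line, by the shift divided by its SE and by the shift itself. The close 7-mers TGAACAA and AGAACAA ranked 2 and 3 in LNCaP and 2 and 7 in PC3 by the shift divided by its SE with adjustment for length and GC content, but 22 and 35 in LNCaP and 21 and 91 in PC3 with length alone. Both hold GAACAA, the part shared by all 3 matches. Their ranks are therefore neither independent of that of GAACAAA nor evidence against a seed effect. CGAACAA, the match to the full seed, was held by too few genes (170) to tell its shift from 0 or from that of genes with GAACAAA alone. A direct effect of miR-375 through GAACAAA is a hypothesis that these data may support only in part, since the planned CGAACAA comparison did not pass and the GAACAAA ranking was found and tested on the same data.

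In LNCaP, 19 genes with at least 1 CPM in the controls had a log2 fold change of −3 or lower, among them TBXT, UCHL1, TGFBI and LGALS3, and 9 of them stood under 1 CPM in the PC3 controls. Reads of PC3 cells in the LNCaP control libraries are argued against: over 31 genes abundant in PC3 and near 0 in LNCaP with miR-375, the upper quartile of the LNCaP to PC3 control ratio was 0.00256. The lost genes had a median ratio of 0.829, a value raised by the 9 that PC3 barely expressed. Lost genes with at least 100 CPM in the PC3 controls ranged from 0.00735 (CDH11) to 0.077 (LGALS3), nearer to 0.00256 but still above it. A minor cell population or foreign RNA of different size in the 2 controls is consistent with the values, as all 19 genes were higher in the first control than in the second. Their median log2 ratio was 0.62 (1.53-fold), and 95% of 10000 random lists matched on expression lay between −0.183 and 0.203. An effect of miR-375 on these genes stays open too, and without the first LNCaP control 5605 genes were called in LNCaP, 2795 higher and 2810 lower.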

How the results depend on the processing

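Halved counts and the fry test were chosen after the data were seen, and the other alternatives before. The number of genes changed in LNCaP, in PC3 and by the interaction was 5795, 7675 and 4527 with DESeq2, 6850, 9503 and 5100 with limma-voom, 6849, 9053 and 5475 with DESeq2's size factors, and 7332, 9274 and 5505 with total counts. It was 6688, 8797 and 5450 without a filter on low counts, 6730, 8046 and 5449 with a filter of 5 CPM, 7288, 9448 and 5604 with halved counts, and 6775, 8969 and 5430 with replicate number as a block. At an adjusted p under 0.01 it was 5325, 7301 and 3995, and at an adjusted p under 0.05 with at least a 2-fold change it was 972, 2226 and 1314, because these thresholds admit fewer genes. With each line fitted alone 7573 genes changed in LNCaP and 9263 in PC3. In fits of fewer libraries the low-count filter was run again on those kept, so the genes tested changed too. Leaving out each library in turn gave 5565 to 7036 genes in LNCaP, 7764 to 9048 in PC3 and 4767 to 4982 for the interaction, where the lone library of a group is assumed to vary like the others.

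The balance of calls in LNCaP depended on scaling, with 3428 higher and 3421 lower under DESeq2's size factors and 4719 and 2613 under total counts, and also on the filter, with 3634 and 3054 without it, and with 3889 and 3399 in halved counts. In PC3 it was 4533 and 4520 under DESeq2's size factors, 5672 and 3602 under total counts and 3721 and 3954 with DESeq2, and 4626 and 4822 with halved counts. For the interaction it was 2735 and 2740, 2686 and 2819, and 2264 and 2263 under these settings. It turned to 3097 and 2353 without a filter and to 3032 and 2572 with halved counts. It also turned without any single LNCaP library, where the genes tested changed too. Of the 31 lists, 9 passed in LNCaP with total counts and 16 in PC3, 3 and 5 with an estimated correlation, 13 and 14 with each line alone, which ended the calls of the endoplasmic reticulum (adjusted p = 0.0685), microRNA machinery (0.101) and respiratory chain (0.0502) lists in LNCaP and of the ribosomal (0.0946) and respiratory chain (0.0507) lists in PC3, and 15 and 14 with the replicate block, which ended the calls of histones in LNCaP (adjusted p = 0.0685) and of the stress response (0.0566), androgen receptor targets (0.0647) and heat shock (0.0739) in PC3. By fry, which tests whether a list's genes move one way and not against other genes, 20 and 24 passed. Without single libraries 13 to 15 lists passed in LNCaP and 13 to 16 in PC3. The epithelial list in PC3 had a median of 0.30 with PC3 fitted alone and its test then pointed down; the cause was not tested. Some lists lost their calls with an estimated correlation under the preset 0.01. They were autophagy (−0.0205) and fatty acid genes (−0.0151) in LNCaP, and YAP/TAZ targets (−0.0244), basal (−0.0120) and epithelial genes (−0.0168) in PC3. For these a higher correlation is argued against as what ended the calls. The other lists that lost calls had higher correlations, up to 0.623. For replication genes in LNCaP the estimate was −0.00646, also under 0.01. The camera p still rose from 2.69e-44 to 8.63e-05. So the 2 forms of the test differ in more than the correlation, and a call lost with an estimated correlation need not be due to correlated genes. What else differed between the 2 forms was not tested.

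For seed sites, genes with any of the 3 matches differed by −0.112 in LNCaP and −0.0861 in PC3, and those with CGAACAAA by −0.0718 in PC3, past the threshold at their unadjusted p. In PC3 neither passed after adjustment over 6 tests (adjusted p = 0.0651 and 0.0732), and with an estimated correlation the genes with any match passed in neither line (p = 0.0699 and 0.138 by camera, n = 2531 genes). A difference between genes with CGAACAA and those with GAACAAA alone was not found, with 95% intervals that held 0 in both lines. Without single libraries the CGAACAA difference ran from −0.106 to −0.0407 in LNCaP and from −0.0269 to 0 in PC3, and with the replicate block it was −0.09 and −0.01. Replicate numbers did not pair the libraries: the correlation across genes of the differences between replicates 1 and 2 of control and miR-375 was 0.0181 in LNCaP and 0.0101 in PC3. Simulated changes of 1.5-fold were found in 72.0% and 77.0% of genes, with 200 of 20051 genes changed in each line and none of these drawn from the genes of lowest control CPM. Far more genes were called in the data, with a median absolute log2 fold change of 0.417 in LNCaP and 0.520 in PC3. No change smaller than 1.5-fold was simulated, so the share of small changes missed in these data is not known.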

Other observations

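The lists of acute-phase and BMP genes were written, and all their tests chosen, after FGB, CP, C3, BMP2 and ID3 had been seen among the largest changes, so they describe these data and are no independent evidence.

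Acute-phase and complement genes, mostly secreted by liver cells, rose in PC3 in 10 of 18 tested cases with 1 lower (median 1.59, camera, adjusted p = 4.04e-06 over 6 tests, and 0.0347 with an estimated correlation). Besides FGB, CP and C3, the complement protease genes C1R and C1S rose from 34.2 ± 1.36 to 106 ± 2.35 CPM and from 18.9 ± 0.216 to 73.6 ± 2.16 CPM. The serum amyloid gene SAA1 rose from 3.56 ± 0.0982 to 13.1 ± 0.0677 CPM and the iron-siderophore-binding gene LCN2 from 14.6 ± 3.32 to 42.9 ± 1.49, while SERPINA1, the gene of alpha-1 antitrypsin, fell from 23.0 ± 0.931 to 15.0 ± 0.291. In LNCaP 1 gene of this list rose and 1 fell, C1R (0.65) and LCN2 (−0.37), and the list did not pass (adjusted p = 0.888). The difference between the lines passed (median −1.97, adjusted p = 2.85e-04, and 0.0440 with an estimated correlation). FGB had no counts in LNCaP.

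Targets of BMP signalling through SMAD proteins rose in PC3 in 8 of 14 tested cases with 2 lower (median 0.73, camera, adjusted p = 0.00184, and 0.249 with an estimated correlation), and BMP2 itself rose from 0.914 ± 0.191 to 14.5 ± 2.30 CPM. The transcriptional inhibitor gene ID1 rose from 252 ± 5.48 to 868 ± 5.08 CPM, ID3 from 31.2 ± 1.26 to 254 ± 4.01 and the feedback inhibitor gene SMAD6 from 47.3 ± 0.224 to 84.2 ± 0.891. NOG, the gene of the BMP antagonist noggin, fell from 39.2 ± 2.45 to 17.1 ± 1.36 CPM and HEY1 by 0.57. In LNCaP none rose and 3 fell (ID2, ID3 and SMAD9; adjusted p = 0.926), the fall of ID3 not holding with total-count scaling, and the difference between the lines passed with the preset correlation (median −0.75, adjusted p = 2.35e-05, and 0.155 with an estimated correlation).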
